A study of Mus musculus with 6 samples.

How the data were processed

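Total RNA of cultured mouse mesangial cells was measured on 6 one-colour oligonucleotide arrays of the mouse 430 2.0 type, 2 each for low glucose, high glucose and glucosamine, per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, from 0 to 12816.4. How the authors summarised probes into probe sets and scaled the arrays is not given in the sources used here, nor are doses and exposure times. Array medians ran from 77.7 to 100.16, a ratio of 1.29, and array means from 283 to 304, a ratio of 1.07. Groups were taken from the sample titles, which mark 3 arrays as repeats, 1 per group, the low glucose one with the number 3. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Their number limits the precision.

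Of the 45101 probe sets, 64 array controls were left out of the tests. Values were taken to log2(intensity + 48), the pseudocount being the 25th percentile of all values rounded to 2 digits, so the fold change of a dim probe set is understated. Because the array medians differed by more than 1.25-fold, the limit fixed before the data were examined, log2 values were quantile normalised. Probe sets with a mean log2 value at or above the median of all probe sets were kept, which left 22519. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 were listed with several genes and 9160 were not listed, and no gene is named from the last 2 kinds. The entrez identifiers of 34741 of the 34945 were found in the RefSeq gene table of the mouse. After the filter 19773 probe sets with 1 symbol stood for 11937 genes, and in gene lists each gene was represented by its probe set with the highest mean.

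Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) over all 6 arrays, two-sided, with Benjamini-Hochberg adjustment over the 22519 probe sets and a threshold of 0.05. This fit, fixed before the data were examined, has no term for the array set. Once the values had been seen, a fit with a block for the array set (3 arrays without a repeat mark in the title against 3 with one) was added, since repeat minus first differences of the 3 groups correlated across probe sets with r from 0.928 to 0.947. Each set holds 1 array of each group, so fold changes are identical with and without the block, and the errors and p-values differ. A block with the 3 kinds of title mark, planned before, was also run. The mark with the number 3 stands on 1 array, the low glucose repeat. That fit therefore spends a term on this array, and low glucose rests on the other 1. The residual degrees of freedom were 3 without a block, 2 with the array set and 1 with the 3 marks.

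Tests were run on simulated data with the real means and array set differences, in which 200 of 22519 probe sets were changed. Errors were drawn independently with the standard deviation of the fit with the block. Better recovery with the block follows from this construction, and it does not show how either fit performs on new cultures. For high glucose against low glucose, limma without the block recovered 0% of changes of 0.5 on the log2 scale, 1.49% of changes of 1 and 48.5% of changes of 2, with 0 false calls; with the block it recovered 100% at each size, with 13 false calls. For glucosamine the corresponding shares without the block were 0%, 1.49% and 53.0% against low glucose and 0%, 2.99% and 50% against high glucose. With the block they were 100% at each size, with 18 and 9 false calls.

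A total of 28 gene lists with 728 entries was written before the data were examined, and 727 entries matched a gene. Some genes stand in several lists, so lists that passed are not all separate results. Lists were tested with camera (preset correlation 0.01; Benjamini-Hochberg over the 28 lists of a comparison), with an estimated correlation and fry beside it. With an estimated correlation camera has at most the residual degrees of freedom, 3 without the block and 2 with it. A list that fails there may fail for that reason, so this does not show that its members are correlated. Members past the threshold were counted over all probe sets and adjusted over the list alone. Genes named in the text followed a rule fixed before: 11 genes of glucose and matrix biology always; the 10 largest rises and falls past the threshold whose arrays did not overlap, or with fewer than 5 of them, the 5 with the smallest unadjusted p in that direction; and of each list up to 4 past the threshold with the largest change, or the 2 largest as values. Of the 11, Col4a1 had no probe set past the filter and one gene is not reported here. Agreement of both treatments was set beside 100 simulated data sets with no effect and the same shared low glucose arrays. Alternatives covered the pseudocount, filter, normalisation, limma prior, arrays in the fit, threshold, block, set test, and leaving out each array. Figures were drawn with matplotlib 3.10.9.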

Results

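Transcript levels were measured in mouse mesangial cells, the contractile, matrix-producing cells of the kidney glomerulus, held in low glucose, in high glucose or with glucosamine, with 2 arrays per group. The labels name the hexosamine pathway and diabetic glomerular disease as the subject. Glucosamine enters the hexosamine pathway beyond the step catalysed by glutamine fructose-6-phosphate amidotransferase, the product of Gfpt1 and Gfpt2, which makes it a comparison for glucose acting through that pathway. After the filter on dim probe sets 22519 probe sets were tested, standing for 11937 named genes. Changes are on the log2(intensity + 48) scale, errors are limma standard errors, and n = 2 arrays per group throughout.

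The 6 arrays fell into 2 sets of 3, those without and those with a repeat mark in the title, each set holding 1 array per group. The first principal component, with 57.9% of the variance, separated the sets, and the next 2 components, with 20.9% and 18.9%, separated the groups. Correlations between arrays ran from 0.971 to 0.977 within a set and from 0.945 to 0.956 between the 2 arrays of a group. Between the sets 312 probe sets differed by more than 2-fold. The ratio of 5' to 3' signal of the beta-actin control was 0.780 to 0.872 on the first arrays and 0.626 to 0.657 on the repeat arrays, and that of pyruvate carboxylase 0.489 to 0.495 and 0.403 to 0.422. The ratio of the dim transferrin receptor control went the other way, from 0.193 to 0.236 on the first and from 0.296 to 0.415 on the repeat arrays, and that of Gapdh overlapped, at 0.961 to 1.025 and 0.991 to 1.025. Fold changes measured within the first set and within the repeat set correlated across probe sets with r = 0.896 for high glucose against low glucose, 0.876 for glucosamine against low glucose and 0.874 for glucosamine against high glucose. Genes are not independent replicates, so these values describe the arrays only. The median standard deviation of a probe set was 0.172 without the array set in the model and 0.0641 with it.

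**Figure D1:**
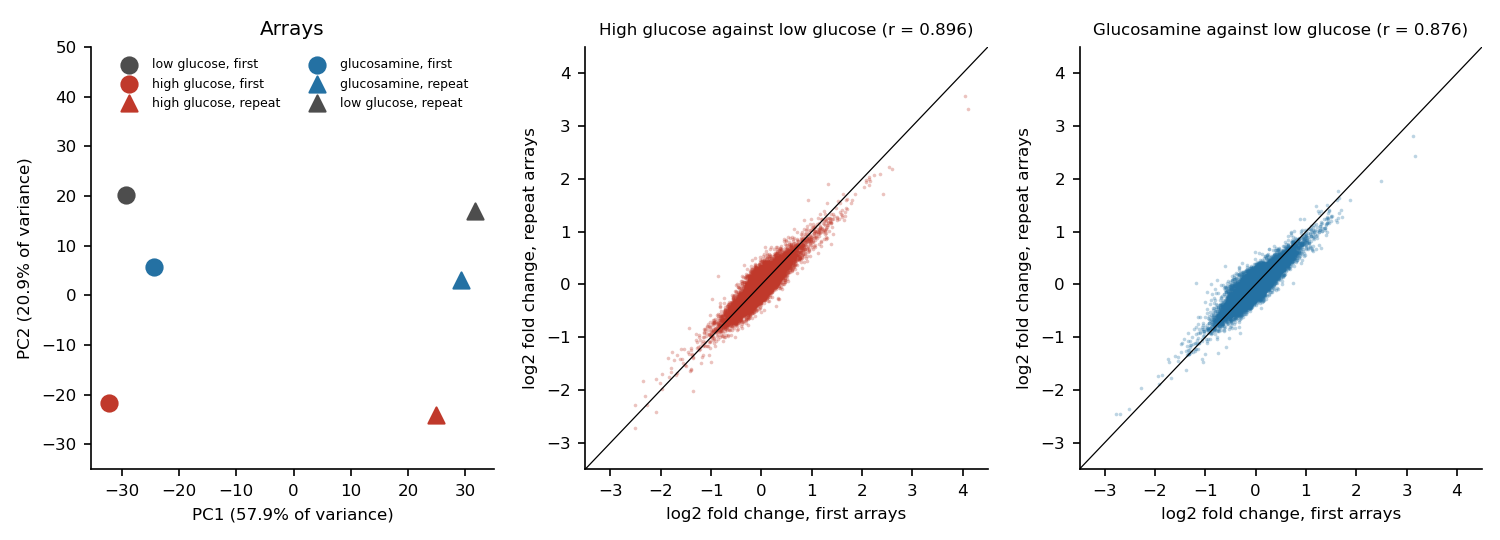
Left, the 6 arrays on the first 2 principal components of the normalised log2 values (axes in component score; colour, group; circle, first arrays; triangle, repeat arrays), with the sets parted along PC1, 57.9% of the variance. Middle and right, log2 fold change of each of the 22519 probe sets within the repeat arrays (y axis) against that within the first arrays (x axis), with the line of equality and correlations of 0.896 and 0.876.

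High glucose was compared with low glucose to find the response of mesangial cells to glucose. Txnip, the glucose-induced inhibitor of thioredoxin, rose 14-fold (log2 change 3.81 ± 0.23, limma adjusted p = 0.0293), by 4.04 within the first arrays and 3.57 within the repeat arrays. Most genes of the ER stress and unfolded protein response list, which holds chaperones and folding enzymes of the endoplasmic reticulum and stress regulators, fell. The median of its 30 measured genes was -1.03, and 28 fell with the array set as a block. Immediate early genes, which are induced within minutes of a growth signal, had a median of 1.03 over 24 genes, of which 23 rose with the block and none fell, though the list did not pass camera with an estimated correlation (adjusted p = 0.109).

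Among the largest rises past the threshold without the block were Fosl1, a subunit of the AP-1 transcription factor (log2 change 2.38 ± 0.20, limma adjusted p = 0.0475), and Tm4sf1, a membrane protein of the tetraspanin-like family (2.06 ± 0.10, adjusted p = 0.0285). Ramp3, a partner of the calcitonin receptor-like receptor, rose by 2.07 ± 0.12 and Angptl4, an inhibitor of lipoprotein lipase, by 2.03 ± 0.12. Plat, tissue plasminogen activator, rose by 1.95 ± 0.14 on one probe set, while its other probe set gave 0.07. Rhob, a small GTPase, rose by 1.70 ± 0.12, the transcriptional inhibitor Id1 by 1.57 ± 0.13, the cell cycle inhibitor Cdkn1a by 1.55 ± 0.11 and Ier2, an immediate early gene, by 1.51 ± 0.11. The limma adjusted p of these 7 genes lay between 0.0285 and 0.0475.

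The largest falls were led by the endoplasmic reticulum proteins Sdf2l1 (log2 change -2.39 ± 0.19, limma adjusted p = 0.0474), Hsp90b1, the chaperone GRP94 (-2.26 ± 0.11, adjusted p = 0.0285), and Creld2 (-2.22 ± 0.13, adjusted p = 0.0285). The disulfide isomerases Pdia6 and Pdia3 fell by 1.99 ± 0.10 and 1.53 ± 0.12; the other probe set of Pdia6 gave -0.43. Ddit3, the stress-induced transcription factor CHOP, fell by 1.67 ± 0.09 and the co-chaperone Dnajc3 by 1.59 ± 0.14. Outside the endoplasmic reticulum Aldh1l2, a mitochondrial folate enzyme, fell by 1.69 ± 0.15, the guidance factor Sema3a by 1.49 ± 0.12 and Acox2, a peroxisomal oxidase, by 1.39 ± 0.12. The limma adjusted p of these 7 genes lay between 0.0285 and 0.0498. Without the block 8 members of the ER stress list fell, 21 when adjusted over the list alone; the list passed camera (adjusted p = 1.14e-27) and passed with an estimated correlation (adjusted p = 0.0291), but not with the block and an estimated correlation (adjusted p = 0.276). Its median was -1.11 within the first arrays and -1.07 within the repeat arrays.

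**Figure D2:**
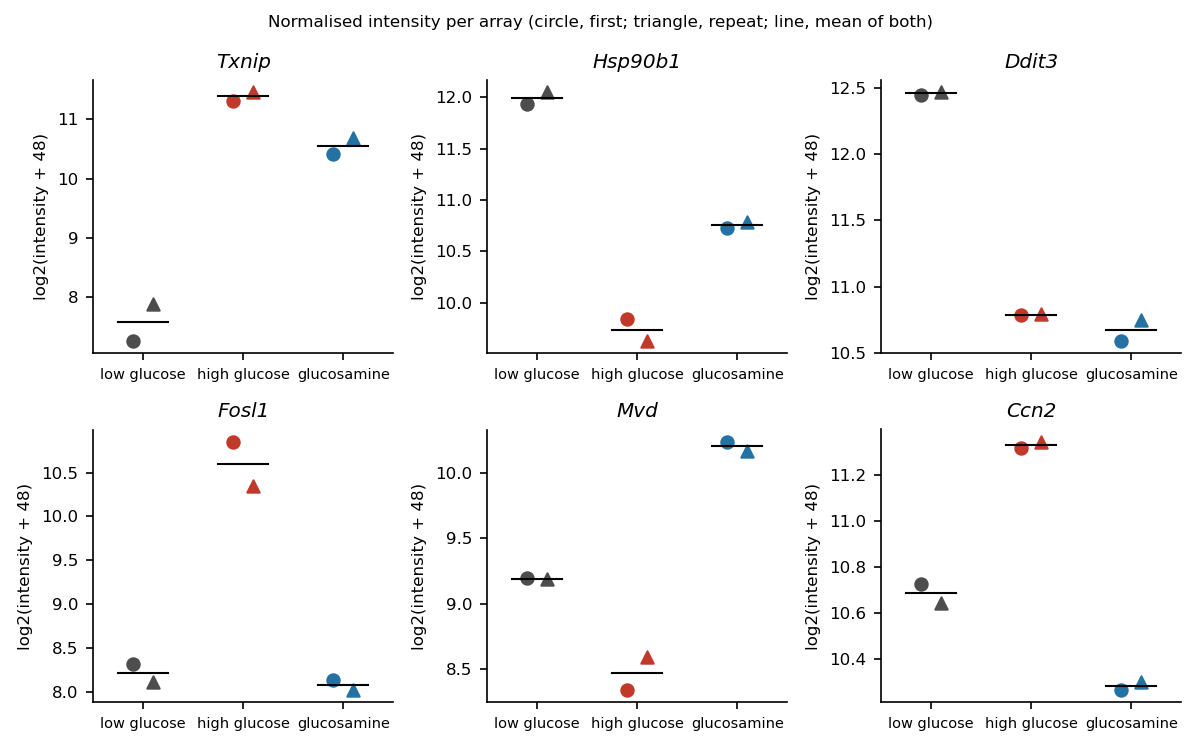
Normalised log2(intensity + 48) of 6 genes on each array (y axis) by group (x axis); circles, first arrays; triangles, repeat arrays; lines, mean of 2 arrays. Each y axis has its own range. Txnip was 3.81 higher in high glucose and 2.97 higher with glucosamine than in low glucose, Hsp90b1 and Ddit3 were lower in both, Fosl1 was 2.38 higher in high glucose, Mvd was 1.01 higher with glucosamine, and Ccn2 was 1.05 lower with glucosamine than in high glucose.

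Of the immediate early genes, 2 rose without the block and 17 when adjusted over the list alone. Jun, an AP-1 subunit, was 2.40 ± 0.23 higher (limma adjusted p = 0.0557), Phlda1 2.0 ± 0.26 higher and Ier5 1.55 ± 0.26 higher. The list passed camera (adjusted p = 5.33e-20; adjusted p = 0.109 with an estimated correlation). Antioxidant genes rose in 20 of 31 cases and fell in 1 with the block, with a median of 0.27, among them Sod3, the extracellular superoxide dismutase (1.48), the glutaredoxin Glrx (1.27) and Nqo1, a quinone reductase (1.22); 13 rose when adjusted over the list alone without the block (camera adjusted p = 8.23e-09; adjusted p = 0.0841 with an estimated correlation). Chemokine and NF-kB genes had a median of 0.39 and rose in 15 of 22 cases with the block, including the chemokines Ccl2 (1.01) and Ccl5 (0.97) and Nfkbia, the inhibitor of NF-kB (1.09; camera adjusted p = 3e-07; adjusted p = 0.109 with an estimated correlation). The cytokine Lif gave 1.30 on one probe set and 0.065 on the other. Ptgs2, the inducible cyclooxygenase, was 1.79 ± 0.21 higher (limma adjusted p = 0.0823). The mitosis list had a median of 0.39, and 20 of 30 genes rose and 1 fell with the block, led by the kinases Aurka (1.19 ± 0.10, limma adjusted p = 0.0475) and Plk1 (1.09; camera adjusted p = 1.05e-07; adjusted p = 0.202 with an estimated correlation).

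Hexosamine pathway genes had a median of -0.36, with 12 of 17 lower and 2 higher at the threshold with the block (camera adjusted p = 1.07e-05; adjusted p = 0.109 with an estimated correlation). Gfpt1 had a log2 change of -1.19 ± 0.15 (limma adjusted p = 0.0908; 2.43e-09 with the block), while its other probe set gave -0.23. Ogt, which attaches N-acetylglucosamine to proteins, had a log2 change of -1.11 ± 0.32 and Amdhd2 one of -0.74 ± 0.14. Cholesterol synthesis genes had a median of -0.26 (13 of 20 lower and 3 higher with the block; camera adjusted p = 0.00378; adjusted p = 0.128 with an estimated correlation). Targets of the glucose sensors ChREBP and MondoA had a median of 0.20 (camera adjusted p = 0.0261; adjusted p = 0.202 with an estimated correlation), including Pdk4, which restrains pyruvate oxidation (1.36), and Arrdc4, an arrestin relative of Txnip (0.76). The TGF-beta pathway had a median of 0.21 (camera adjusted p = 0.000144; adjusted p = 0.128 with an estimated correlation), with Id1, Id3 (1.39) and the TGF-beta family antagonist Fst (1.65) highest. Of the matrix genes fixed beforehand, Ccn2 had a log2 change of 0.65 ± 0.08, Fn1, fibronectin, 0.37 ± 0.24 and Tgfb1 0.26 ± 0.14, each past the threshold only with the block. The glucose transporter Slc2a1 had a change of 0.21 ± 0.33 and also passed with the block (limma adjusted p = 0.0013), while Gfpt2, at 0.02 ± 0.56, passed in neither fit.

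The other lists past camera without the block were matrix turnover (0.21, adjusted p = 0.128 with an estimated correlation), cell cycle inhibitors and p53 targets (0.28, adjusted p = 0.128), proteoglycans (0.08, adjusted p = 0.139), DNA replication (0.14, adjusted p = 0.139), glycolysis (0.14, adjusted p = 0.165), extracellular matrix (0.12, adjusted p = 0.202), oxidant sources (0.12, adjusted p = 0.202) and mesangial and contractile markers (0.28, adjusted p = 0.321), each with an estimated correlation. Lists that did not pass were the amino acid response (0.02), polyol and pentose phosphate pathways (0.04), hypoxia (0.15), fatty acid metabolism (-0.07), interferon-stimulated genes (0.04), cytosolic heat shock (0.08), oxidative phosphorylation (-0.02), and markers of podocytes (0.12), endothelium (0.04), tubule (0.13) and leukocytes (-0.07). In all, 42 probe sets passed limma without the block, 23 higher and 19 lower in high glucose, and 9396 with it, 4579 higher and 4817 lower (4953 and 4628 with cyclic loess), of which 130 and 77 changed at least 2-fold. Of the 28 lists, 17 passed camera without the block and 16 with it, which ended the call of extracellular matrix (adjusted p = 0.107). With the block and an estimated correlation 0 passed (lowest adjusted p = 0.276). The 42 calls fell to 0 without any 1 of the 6 arrays.

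Glucosamine was compared with low glucose to find the response of the same cells to glucosamine; the labels do not give the glucose level of that group. Txnip was 7.85-fold higher (log2 change 2.97 ± 0.08 with the block, limma adjusted p = 4.17e-11), by 3.14 within the first arrays and 2.81 within the repeat arrays. ER stress genes had a median of -1.0, and 27 of 30 fell with the block while none rose. Cholesterol synthesis genes rose in 19 of 20 cases, with a median of 0.73, and interferon-stimulated genes, the antiviral response, in 20 of 25 cases, with a median of 0.48. Genes of the amino acid response fell in 24 of 30 cases, with a median of -0.42, and 3 rose. With an estimated correlation and no block ER stress passed camera and the others did not (adjusted p = 0.0513 for cholesterol synthesis and 0.0535 for the interferon and amino acid lists). The counts of genes are of limma with the block; without it 0 probe sets passed at an adjusted p of 0.05, 34 at 0.10, 15 higher and 19 lower, and 2346 had an unadjusted p under 0.05.

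The genes with the smallest unadjusted p without the block are given as values in that fit. Higher with glucosamine were Id1 (log2 change 1.74 ± 0.13), Agt, the precursor of angiotensin (1.61 ± 0.10), and S100a4, a calcium-binding protein (1.44 ± 0.10). So were the acyl-CoA-binding protein Dbi (1.39 ± 0.08) and Uqcrh, a subunit of respiratory complex III (1.0 ± 0.08). Lower were Snhg12 (-2.12 ± 0.13) and Snhg1 (-1.90 ± 0.10), both host transcripts of small nucleolar RNAs, and Ddit3 (-1.79 ± 0.09). The stress-induced transcription factor Atf3 (-1.35 ± 0.09) and Hspa5, the chaperone BiP (-0.82 ± 0.06), were lower too. The limma adjusted p of all these genes without the block lay between 0.0519 and 0.0676, and each passed with the block.

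Of the ER stress genes Creld2 fell by 1.84, Sdf2l1 by 1.72 and Ppp1r15a, which restores translation after stress, by 1.5 (camera adjusted p = 1.4e-24; adjusted p = 0.0348 with an estimated correlation, and 0.322 with the block as well). Without the block 0 passed over all probe sets and 23 fell when adjusted over the list alone. Cholesterol genes were led by the reductase Dhcr7 (1.65), Nsdhl (1.43), Hmgcs1, which makes the precursor of mevalonate (1.06), and Mvd, mevalonate decarboxylase (1.01); 14 rose without the block when adjusted over the list alone (camera adjusted p = 4.17e-13; adjusted p = 0.0513 with an estimated correlation). Interferon-stimulated genes were led by Oasl2 (1.45), Ifit3 (1.02) and Usp18 (0.91; 8 adjusted over the list alone; camera adjusted p = 1.39e-09; adjusted p = 0.0535 with an estimated correlation). In the amino acid response, Atf3, Nupr1 (-0.96) and the arginine transporter Slc7a1 (-0.70) fell with the block, as did 7 genes without it when adjusted over the list alone (camera adjusted p = 2.52e-10; adjusted p = 0.0535 with an estimated correlation).

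Fatty acid metabolism had a median of 0.32, with Elovl6, which lengthens fatty acids (1.56), and Fasn, fatty acid synthase (0.68), among 17 of 26 genes that rose with the block (camera adjusted p = 6.75e-07; adjusted p = 0.0557 with an estimated correlation). ChREBP and MondoA targets share Elovl6 and Fasn with the fatty acid list. These targets had a median of 0.37 and rose in 12 of 17 cases with the block (camera adjusted p = 2.37e-07, and 0.0659 with an estimated correlation). Mitosis genes had a median of 0.39 and rose in 22 of 30 cases (camera adjusted p = 1.19e-10, and 0.193 with an estimated correlation). Further lists past camera were antioxidant defence (median 0.23, adjusted p = 0.0659 with an estimated correlation), glycolysis (0.28, adjusted p = 0.0822), oxidative phosphorylation (0.12, adjusted p = 0.193), TGF-beta pathway (0.22, adjusted p = 0.264), proteoglycans (0.12, adjusted p = 0.178), cell cycle inhibitors (0.10, adjusted p = 0.248) and polyol and pentose phosphate pathways (0.06, adjusted p = 0.178). Hexosamine pathway genes had a median of 0.04 and did not pass; with the block 5 of 17 fell, led by Gnpnat1 (-1.05), Ogt (-0.71) and Gfpt1 (-0.64), and 3 rose, Gnpda1 (0.43), Nagk (0.19, with -0.059 on its other probe set) and Uap1l1 (0.14). Fn1 (-0.57 ± 0.04) and Ccn2 (-0.40 ± 0.05) fell with the block, while Tgfb1 (0.37 ± 0.06) and Arrdc4 (0.78 ± 0.06) rose. Slc2a1 also fell with the block (-0.18 ± 0.04, limma adjusted p = 0.00403), and Gfpt2 had a change of 0.10 ± 0.09 that did not pass. Medians of immediate early genes (0.05), chemokines (0.00) and extracellular matrix (0.06) were near 0, and markers of podocytes (0.04), endothelium (0.09), tubule (0.05) and leukocytes (0.09) did not pass. With the block 9258 probe sets passed limma, 4531 higher and 4727 lower, 91 and 64 of them by at least 2-fold. Of the 28 lists 14 passed camera without the block, 12 with it, and 0 with the block and an estimated correlation (lowest adjusted p = 0.322). The block ended the calls of cell cycle inhibitors (adjusted p = 0.0848) and of polyol and pentose phosphate pathways (adjusted p = 0.148).

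**Figure D3:**
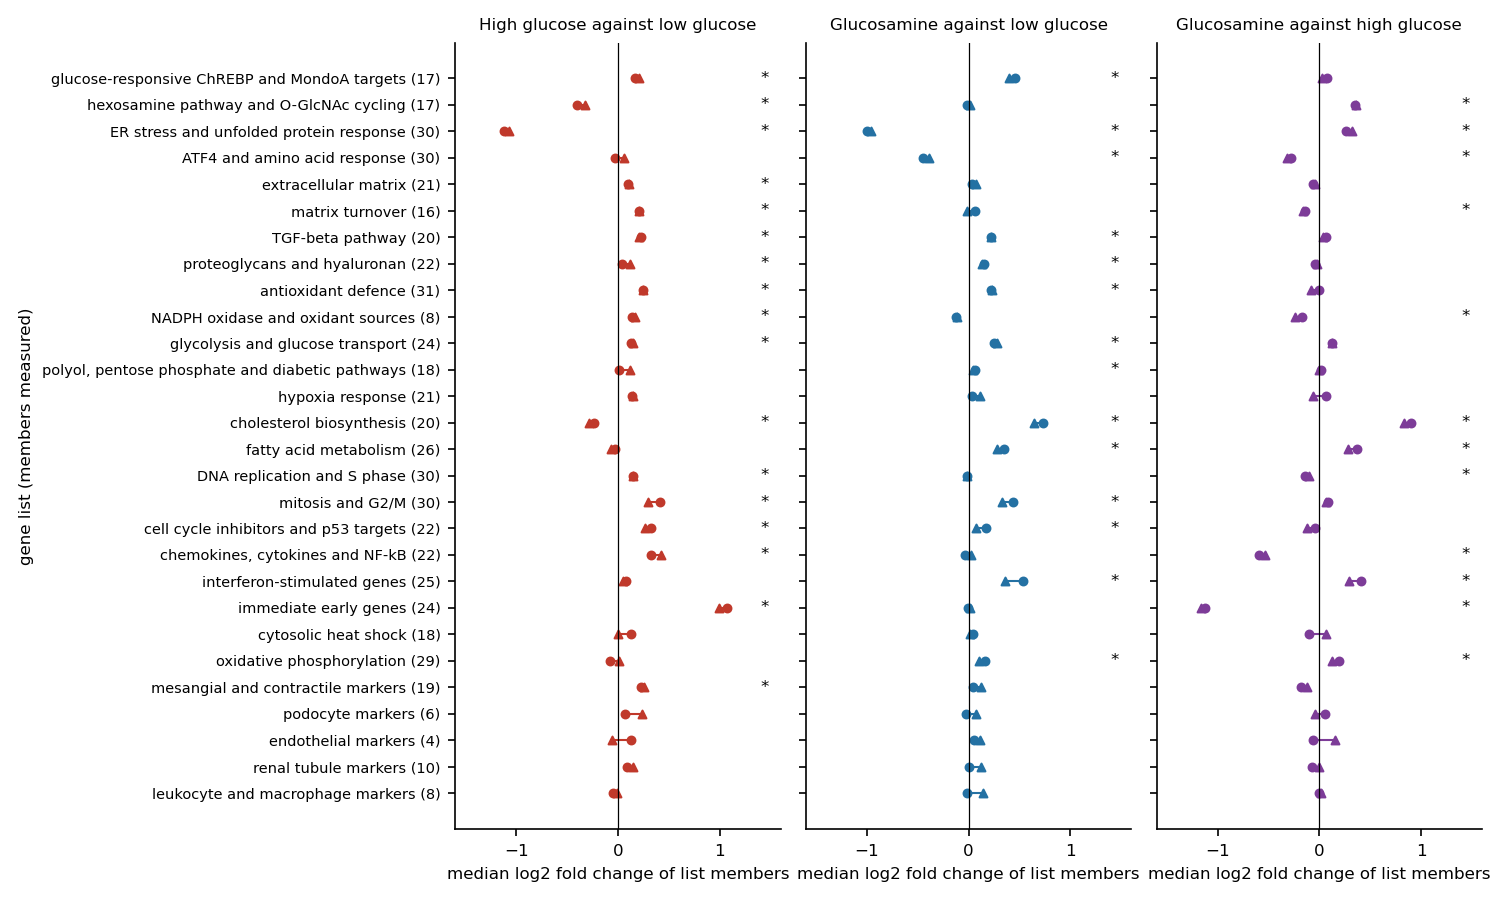
Median log2 fold change of the members of each of the 28 gene lists (x axis) in the 3 comparisons, within the first arrays (circles) and within the repeat arrays (triangles); the number of members measured stands in brackets and an asterisk marks a camera adjusted p under 0.05 without the block. ER stress genes lay at -1.11 and -1.07 in high glucose and at -0.99 and -0.95 with glucosamine, against low glucose.

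Glucosamine was set directly against high glucose to test where both treatments differed. Immediate early genes were lower with glucosamine, with a median of -1.18, and 21 of 24 fell with the block while none rose. Cholesterol synthesis genes were higher, with a median of 0.86, and 18 of 20 rose. Chemokine and NF-kB genes fell in 15 of 22 cases with a median of -0.55, and interferon-stimulated genes rose in 19 of 25 cases with a median of 0.34. None of these 4 lists passed camera with an estimated correlation (adjusted p = 0.0657 for cholesterol synthesis and 0.0725 for the others). Fn1 and Ccn2, both matrix-associated, were lower by 0.94 ± 0.04 and 1.05 ± 0.05 with the block (log2 changes -0.94 and -1.05, limma adjusted p = 1.85e-09 and 1.76e-09). The counts of genes are of limma with the block; without it 0 probe sets passed at 0.05 (smallest adjusted p = 0.0553), 92 at 0.10, 21 higher and 71 lower, and 2311 had an unadjusted p under 0.05.

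The smallest unadjusted p values without the block belonged to genes given here as values in that fit. Lower with glucosamine were Ramp3 (log2 change -2.44 ± 0.12), Atf3 (-1.88 ± 0.09), Ier2 (-1.70 ± 0.11), Tm4sf1 (-1.62 ± 0.10) and Snhg1 (-1.58 ± 0.10). Higher were Idh1, the cytosolic isocitrate dehydrogenase (1.83 ± 0.11), Mvd (1.74 ± 0.13), Nrep (1.66 ± 0.14), Agt (1.16 ± 0.10) and Hmgcs1 (1.12 ± 0.09). Their limma adjusted p without the block lay between 0.0553 and 0.076, and each passed with the block.

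Within the immediate early list Jun fell by 2.53, Fosl1 by 2.52 and Fos by 1.93 with the block, and 16 genes fell without it when adjusted over the list alone (camera adjusted p = 2.71e-20; adjusted p = 0.0725 with an estimated correlation). Cholesterol genes, besides Mvd, were led by Nsdhl (1.55), Dhcr7 (1.40) and Tm7sf2 (1.34; 16 adjusted over the list alone; camera adjusted p = 1.17e-17; adjusted p = 0.0657 with an estimated correlation). Lcn2, an iron-scavenging secreted protein, fell by 1.79 and Ccl2 by 1.02 in the chemokine list (camera adjusted p = 5.73e-09; adjusted p = 0.0725 with an estimated correlation). Ifit3 (1.44) and Bst2 (0.91) led the interferon-stimulated genes (camera adjusted p = 7.5e-08; adjusted p = 0.0725 with an estimated correlation). Sod3 fell by 1.78, Hmox1, heme oxygenase, by 1.01 and Ptgs2 by 1.93 with the block. Fatty acid genes had a median of 0.29, with Scd2, a desaturase, at 0.96 (camera adjusted p = 1.23e-05; adjusted p = 0.0725 with an estimated correlation). Oxidative phosphorylation genes rose in 23 of 29 cases with a median of 0.15 (camera adjusted p = 1.23e-05; adjusted p = 0.139 with an estimated correlation).

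With glucosamine against high glucose the ER stress list had a median of 0.30, and 18 of 30 genes rose and 6 fell with the block, among them Hsp90b1 (1.02), Pdia6 (0.82) and Sel1l (0.80) upward and Ppp1r15a (-1.34) downward (camera adjusted p = 0.00138; adjusted p = 0.11 with an estimated correlation). The other probe set of Pdia6 gave 0.055. Amino acid response genes had a median of -0.28 (22 of 30 lower with the block; camera adjusted p = 7.5e-08; adjusted p = 0.0725 with an estimated correlation). Hexosamine genes had a median of 0.33, with 12 of 17 higher, such as Gnpda1 (0.82) and Amdhd2 (0.81; camera adjusted p = 0.00228; adjusted p = 0.125 with an estimated correlation). Gfpt1 gave 0.55 on one probe set and -0.35 on the other, so its direction is open. Txnip was 0.84 ± 0.08 lower than in high glucose (log2 change -0.84, adjusted p = 3.35e-06 with the block). Slc2a1 was lower by 0.39 ± 0.04 (log2 change -0.39, limma adjusted p = 8.35e-06 with the block) and Ogt higher by 0.41 ± 0.06 (limma adjusted p = 7.32e-05 with the block), while Tgfb1 (0.11), Gfpt2 (0.08) and Arrdc4 (0.02) did not pass. Matrix turnover (-0.15, adjusted p = 0.128 with an estimated correlation), DNA replication (-0.12, adjusted p = 0.148) and oxidant sources (-0.20, adjusted p = 0.218) also passed camera with the preset correlation. With the block 9580 probe sets passed limma, 4903 higher and 4677 lower with glucosamine, 68 and 113 of them by at least 2-fold. The larger side turned with the scaling, to 4274 higher and 4743 lower without normalisation and 4457 and 5049 with cyclic loess. Of the 28 lists 12 passed camera without the block, 13 with it, adding mesangial markers (median -0.14, adjusted p = 0.0335), and 0 with an estimated correlation in either fit.

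The changes of both treatments against low glucose were compared to see how far glucosamine moved the same genes as high glucose. ER stress genes had medians of -1.03 in high glucose and -1.0 with glucosamine, cholesterol synthesis genes of -0.26 and 0.73, and immediate early genes of 1.03 and 0.05. With the block 2132 probe sets rose in both treatments and 2489 fell in both, against 921 and 1011 for independent lists of the same sizes, while 475 rose in high glucose and fell with glucosamine and 390 did the reverse, against 961 and 969. Simulated data with no effect and the same shared low glucose arrays gave a mean of 0.06 probe sets past the threshold in both. The first of these values leaves out the shared arrays and the second the effects, so the excess over neither measures a shared effect. Fold changes correlated across probe sets with r = 0.502, but the same simulations gave a mean r of 0.50 (range 0.489 to 0.513). The covariance of the fold changes was 0.0383 against 0.00206 in the simulations, a difference of 0.0362. It was 0.0221 without a filter, and 0.0836 and 0.0778 without the first or the repeat low glucose array, when the sets no longer balance. With high glucose against low glucose taken within one array set and glucosamine against low glucose within the other, so that no array was shared, the covariance was 0.0356 and 0.0369 and r was 0.458 and 0.439, a comparison chosen after seeing the data. The overlap counts cannot be split this way, with 1 array per group in a set, and part of their excess may come from the shared arrays. If the repeat arrays hold the same RNA as the first ones, the low glucose culture stays shared across the sets. The simulations drew errors between arrays only, with no spread between cultures. The covariance therefore cannot tell a response shared by both treatments from a low glucose culture that deviated.

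**Figure D4:**
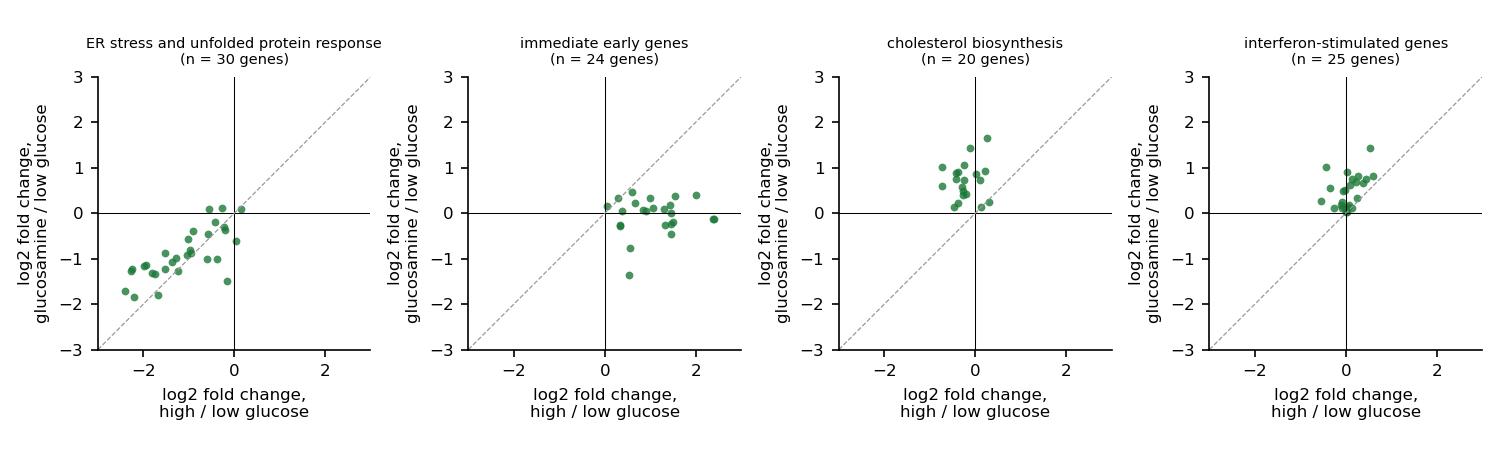
Log2 fold change with glucosamine (y axis) against that in high glucose (x axis), both relative to low glucose, for the measured members of 4 gene lists (1 point per gene; dashed line, equal change; mean of 2 arrays per group). ER stress genes lie low on both axes, with medians of -1.03 and -1.0, immediate early genes have a median of 1.03 in high glucose and 0.05 with glucosamine, and cholesterol genes of -0.26 and 0.73.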

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

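The comparison within sets and the glucose shortage test were chosen after their results had been seen; both scaling tests were set before. All of these explanations are hypotheses, found and tested on the same 6 arrays.

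A control probe set for the B2 repeat element stood out because it is outside the comparisons of the report and was brighter in high glucose than in low glucose, by 1.71-fold over both sets (1.44-fold on the first arrays and 2.02-fold on the repeat arrays); a second, far brighter B2 control was 1.21-fold higher on both. The 5' control probe set of beta-actin was brighter in high glucose by 1.30-fold (1.27-fold and 1.33-fold), and its middle and 3' probe sets by 1.26-fold and 1.2-fold. These control ratios are of intensities before normalisation. Cholesterol synthesis genes, 20 in all, had a median log2 change of -0.26 in high glucose (13 fell and 3 rose with the block) and of 0.73 with glucosamine (19 rose), and the direct comparison of glucosamine with high glucose gave 0.86, with 18 rising and none falling. The list passed camera in each comparison, but not with an estimated correlation (adjusted p = 0.128, 0.0513 and 0.0657).

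The 3 repeat arrays differed from the 3 first arrays in a way shared by low glucose, high glucose and glucosamine: the lowest correlation between 2 groups of the repeat minus first differences was 0.928 across probe sets. An intensity-dependent scaling curve between the sets is argued against, since cyclic loess left the lowest correlation at 0.930. Bacterial BioB, BioC and BioD and phage Cre controls, which do not come from the cells, were brighter on the repeat arrays before normalisation. BioB-3 read 142 to 157 on the first arrays. On the repeat arrays it read 308 in high glucose, 407 in low glucose and 548 with glucosamine. The sets therefore differed in more than the cells. Whether the repeat arrays held new cultures or the same RNA, labelled or hybridised apart, stays open, because either could give such a shared difference and the labels do not say, and no biological explanation was tested.

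ER stress genes such as Hsp90b1, Creld2 and Ddit3 were lower in both treatments than in low glucose. A fault of the arrays of one set alone is argued against, since the highest of the 4 medians within a set was -0.955 (2 treatments, 2 sets). Scaling of the arrays is argued against, since over 4 scalings the highest median was -0.987. One candidate explanation is that glucose ran short in the low glucose culture and raised these genes there. Such a shortage might also raise the amino acid response list, which fell with glucosamine. In high glucose the median of that list, the higher of the 2, was 0.022. There the list was split, with 13 of 30 genes lower and 6 higher with the block. A glucose shortage therefore stays open. The difference in glucose or glucosamine supply that the design names also stays open, as no untreated reference beyond low glucose is held here.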

How the results depend on the processing

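The block for the first against the repeat arrays, alone and with other choices, and the covariance across the array sets were chosen after seeing the data; all other alternatives were planned. With an array left out, the lone array of its group is assumed to vary like the other groups. Without the block, the count of probe sets past limma for high glucose against low glucose (42) was 36 with a pseudocount of 1, 45 with the median as pseudocount, 11 without a filter, 93 with the stricter filter, 36 without normalisation, 38 with cyclic loess, 12 with median centring, 10 without the intensity trend, 14 with the robust prior, 0 with only the 4 arrays compared, 135 at adjusted p under 0.10, and 0 with each array left out, when all 23 calls of named genes were lost too. For glucosamine against low glucose (0) it was 2 with a pseudocount of 1, 29 with the stricter filter, 9 without normalisation, 12 with cyclic loess and 34 at 0.10. For glucosamine against high glucose (0) it was 6 with the median as pseudocount, 29 with the stricter filter and 92 at 0.10. The other alternatives gave 0 for both; dropping an array removes residual degrees of freedom and fewer probe sets tested ease the adjustment, and the cause of the other shifts was not tested.

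With the first against repeat block the counts were 9396, 9258 and 9580, and with a block of 3 title marks 6551, 6824 and 9513. The first against repeat counts stayed within 1.5 times under every alternative run with that block, including each array left out (6514 to 10368, 6820 to 9792 and 7437 to 9593). The block changed the call of 233 of 266 named results and turned none, because each set holds 1 array per group. Its small error may be that of repeated measurement of the same RNA, so it does not carry over to new cultures.

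Camera's 17, 14 and 12 lists became 1, 1 and 0 with an estimated correlation and 0, 0 and 0 with the block and an estimated correlation; fry, which does not compare a list with other genes, gave 22, 18 and 21 with the block. Without the block the estimated correlation was -0.013 for ER stress genes, below the preset 0.01, and 0.262 for mitosis genes. For ER stress genes the higher p therefore came from the 3 residual degrees of freedom. For mitosis genes the correlation may add to it. In none of the other alternatives run did these counts move by over 1.5 times. In 2, 6 and 3 lists, none past the threshold, median, mean and test differed in sign. The covariance of both treatments' changes (0.0383) was 0.0515 with a pseudocount of 1, 0.0314 with the median, 0.0221 without a filter, 0.0560 with the stricter filter, 0.0389 without normalisation, 0.0388 with cyclic loess, 0.0389 with median centring 0.0346 to 0.0836 with each array left out, and 0.0356 and 0.0369 across the array sets with no low glucose array shared; it remained above 0, and the cause was not tested.

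Of named genes only ones with small changes turned sign, each when an array was left out so that the sets no longer balanced. Some of these changes had passed limma with the block, such as Slc2a1 (0.212) and Eng (0.242) in high glucose. Against low glucose the ranges in high glucose were -0.58 to 0.64 for Gfpt2, -0.091 to 0.51 for Slc2a1, -0.041 to 0.53 for Eng and -0.064 to 0.18 for Esam, and with glucosamine -0.51 to 0.71 for Gfpt2, -0.47 to 0.11 for Slc2a1, -0.58 to 0.19 for Rac2 and -0.15 to 0.41 for Eng. Glucosamine against high glucose gave -0.41 to 0.55 for Gfpt2, -0.40 to 0.17 for Eng, -0.037 to 0.21 for Esam and -0.48 to 0.04 for Cd68. No scaling gave a median log2 change over all tested probe sets above 0.025 in size. Quantile normalisation and median centring hold this median near no change by construction, and the authors' own scaling is not known. It therefore cannot exclude a shift of all genes. Dim probe sets near the pseudocount are limited by background, which compresses their changes.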

Other observations

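The genes this part opens with and the test of nuclear RNAs with Neat1 were chosen after their values had been seen; the tests of further host genes and ribosomal protein genes were set before. Long non-coding transcripts that carry small nucleolar RNAs in their introns were among the lowest genes with glucosamine. Against low glucose Snhg5 had a log2 change of -2.58 and Zfas1 of -1.27, beside Snhg1 and Snhg12, and all 4 fell in limma with the array set as a block (n = 2 arrays per group), while another probe set of Snhg5 gave -0.059. In high glucose the same 4 genes had a median of -0.50, and glucosamine lay below high glucose by a median of -1.50. Neat1, the scaffold of nuclear paraspeckles, fell by 1.48 with glucosamine on one probe set, and its other probe set gave 0.042. Malat1, another nuclear RNA, rose by 1.66 in high glucose with the block on its brightest probe set and had a change of 0.35 with glucosamine; its lowest probe set in high glucose gave -0.11.

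The fall of Snhg1, Snhg5, Snhg12 and Zfas1 raised the hypothesis that it extends to other hosts of small nucleolar RNAs. Of 16 further host genes 10 were measured: 6 fell with glucosamine with the block, among them Snhg17 (-1.32), Snhg16 (-1.24) and Gas5 (-1.03), 1 rose, Snhg18 (0.65), and 3 did not pass. Their median was -0.41, at the 0.01 percentile of 10000 random lists matched on mean expression, which is consistent with a decrease that reaches part of this class; it was -0.459 within the first arrays and -0.361 within the repeat arrays. Against high glucose their median was smaller, -0.163 (-0.295 and -0.056 within the sets), and 5 fell and 2 rose. The other probe set of Snhg16 gave -0.06. A fall of a like size in all genes with a terminal oligopyrimidine start is argued against. The 42 ribosomal protein genes measured had a median of -0.04, with values from -0.465 to 0.208. With the block 12 of them fell and 4 rose, beside 4727 and 4531 of all 22519 probe sets. The median of -0.04 lay at the 0.02 percentile of random lists. This percentile does not by itself show a fall, since against high glucose a median of 0.017 lay at the 0.93 percentile. Less nuclear long non-coding RNA as such stays open: 8 such RNAs had a median of -0.051, at the 16th percentile of random lists (3 fell and 1 rose with the block), but they leave out Neat1, which fell, and the 9 with Neat1, at -0.151 and the 2.25 percentile, include the gene that raised the idea. What lowered these transcripts was not tested.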
